A study of Homo sapiens with 6 samples.

How the data were processed

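RNA from xenograft tumors and from cultured SNU-601 cells was labelled with Cy5 and Cy3 and hybridised to cDNA arrays with 23232 genes and 1056 controls, per the labels and the series' design text. The authors scanned the slides with a GenePix 4000B scanner, read them with GenePix Pro 4.0 and normalized them with the print-tip lowess method of the marray package, per the same text. The deposited values are log2 ratios per spot, with medians between -0.00 and 0.01 on the 6 arrays. The log base and the direction are not written in the table: base 2 and tumor over cells follow from the package's definition and the dyes. Background correction and spot filters are not given in the sources used here. Spot intensities were not analysed here, so no signal over background can be given, and control spots could not be told from others and stayed in. All arrays had the same dye orientation.

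Groups were taken from the sample labels, 3 arrays of control tumors and 3 of LRRC3B tumors. A platform annotation named 18597 of the 24288 spots with 1 gene symbol, 70 with several and 5621 with none. Of 18667 annotated probes 18563 matched a gene identifier in a RefSeq table of assembly GRCh38.p14, which was used for names only and changed 0 symbols. Genome positions were not used. Probes of 1 gene were averaged on each array, and a probe with no or several symbols stayed a feature of its own. Of 14491 features 14297, 8798 of them genes, had values on at least 2 arrays per group and were tested. For 37 of the 4411 genes with several probes, the probes' means differed by over 2 log2 units.

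Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 with statmod 1.5.0, using 1 coefficient per group, eBayes and Benjamini-Hochberg adjustment at 0.05. The comparisons were LRRC3B tumor minus control tumor, in which the reference and any dye effect cancel, the mean of both groups against 0, and each group against 0. The 29 gene lists were fixed before the data were examined, as were the main design and the other ways of processing listed below, apart from those named as added. The 26 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, two-sided, and also with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Erythroid, skeletal muscle and fat, and metallothionein lists had 3 measured members each and were not tested.

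Genes were named by a rule fixed before the data were examined. For LRRC3B against control tumors it took 12 per direction, those past the adjusted threshold first and then those with the smallest p whose groups did not overlap. For tumors against cells it took the 12 largest per direction among those called with one sign on all arrays. For each list it took up to 4 called members with the smallest p, or 2 members as values where none was called. Placeholder symbols were not named, and not every gene the rule takes is printed.

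Alternatives covered missing values, scaling between arrays, single probes, robust eBayes, array weights, each array left out, the replicate number as a block and other thresholds. The median of a gene's probes, and scaled or quantile-normalized arrays for the lists, were added after seeing the data. The method was tested on simulated data with 200 changed features among 14297, using the spread of the real arrays. For LRRC3B against control tumors it recovered 26.6%, 75.8% and 96.1% of features changed by 0.5, 1 and 2 log2 units, with 8.3 false calls per simulation. For tumors against cells it recovered 74.9%, 94.9% and 98.3%, with 7.6 false calls.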

Results

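Gene expression was measured in xenograft tumor RNA on 6 cDNA arrays of 2 colours each. SNU-601, a human gastric cancer cell line, had been given either an empty vector or stable expression of LRRC3B, a leucine-rich repeat protein, and was injected under the skin of 3-week-old male nude mice, which lack a thymus. Tumors were removed 57 days after injection. Each array carried tumor RNA in the Cy5 channel and RNA of cultured SNU-601 cells in the Cy3 channel, 20 µg of each. There were 3 control tumor arrays and 3 LRRC3B tumor arrays. Of the 24288 spots, 24085 to 24155 had a value on each array, and the number of arrays limits the precision. Values are log2 ratios, taken here as tumor over cultured cells. That direction is likely rather than stated: it rests on the dyes, on how the normalization package defines its ratio, and on collagen probes being positive on every array. If it were turned, every sign below would turn. The labels do not say whether the arrays of a group came from separate animals. Limma's p-values thus measure only the spread between these arrays, which may be technical. Camera at the preset correlation weighs a list's genes against the other genes, so its p-values do not measure agreement between arrays.

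LRRC3B itself could not be followed, because 0 of the annotated probes carried its symbol or gene identifier. The overexpressed gene therefore gives no check of the labels here. Correlations over spots ran from 0.576 to 0.786 between arrays of one group and from 0.479 to 0.745 between arrays of different groups.

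The first comparison asked how LRRC3B tumors differed from control tumors. Of the 9 features at an adjusted p under 0.10, OAS1, IFI27 and IFI44 are targets of interferon, UCA1, DHRS4, PSMG2 and DMKN are not in the interferon list used, and 2 carry no gene symbol. OAS1, an antiviral 2'-5'-oligoadenylate synthetase, differed by 0.88 ± 0.08 (log2, SE, n = 3 arrays per group), IFI27 by 1.05 ± 0.10 and IFI44 by 1.02 ± 0.10, all with the higher value in LRRC3B tumors. BST2, a membrane protein that tethers virions, differed by 1.43 ± 0.19 at an adjusted p of 0.137. No single gene passed the test, however: limma with Benjamini-Hochberg adjustment called 0 of 14297 features, and the smallest adjusted p was 0.0597. At an unadjusted p under 0.05 limma gave 1443 features, 931 with the higher value in LRRC3B tumors and 512 with the lower, where 715 are expected by chance. The 2 groups did not overlap for 2421 of the 14179 features with a value on every array, or 17.1%, against 10% by chance. Both chance values are averages from which single groupings can lie far. Other splits of the arrays into 3 and 3 gave from 249 to 1579 features at an unadjusted p under 0.05.

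The values of the named genes that ranked first are given without calling them changed. The feature with the smallest p was a probe without a symbol, at 1.51 ± 0.12 (adjusted p 0.0597), and a further one was at 1.22 ± 0.12, so some of the leading features are unidentified. The first of these was the 1 feature called with only complete features and the 1 called with robust eBayes. With the higher value in LRRC3B tumors were also the non-coding RNA UCA1 (0.92 ± 0.09), the reductase DHRS4 (0.98 ± 0.10), LGALS9, which encodes galectin-9 (0.81 ± 0.10), PRR13 (1.01 ± 0.13), SLC6A13 (0.69 ± 0.09), ANKRD1 (0.85 ± 0.12), HLA-C, a class I antigen-presenting molecule (1.02 ± 0.14), and CALCOCO1 (0.62 ± 0.09). With the lower value were PSMG2, a proteasome assembly chaperone (-0.83 ± 0.09), DMKN (-0.93 ± 0.10), SMARCE1, a chromatin remodelling subunit (-0.72 ± 0.08), PITRM1 (-0.88 ± 0.13), ARG1, which encodes arginase (-1.06 ± 0.16), DMTN (-0.89 ± 0.14), the arginine methyltransferase PRMT1 (-0.63 ± 0.10), PARP3 (-0.46 ± 0.08), DGAT1 (-0.57 ± 0.10), ISOC2 (-0.45 ± 0.08), PCM1 (-0.51 ± 0.09) and ZNF26 (-0.50 ± 0.09). Adjusted p ran from 0.0597 for OAS1 to 0.217 for ZNF26. The count of calls depended on single choices: array weights called 13 features, among them OAS1, IFI27, IFI44, HLA-C, PSMG2 and DMKN, and leaving out LRRC3B tumor 2 called 6.

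**Figure D1:**
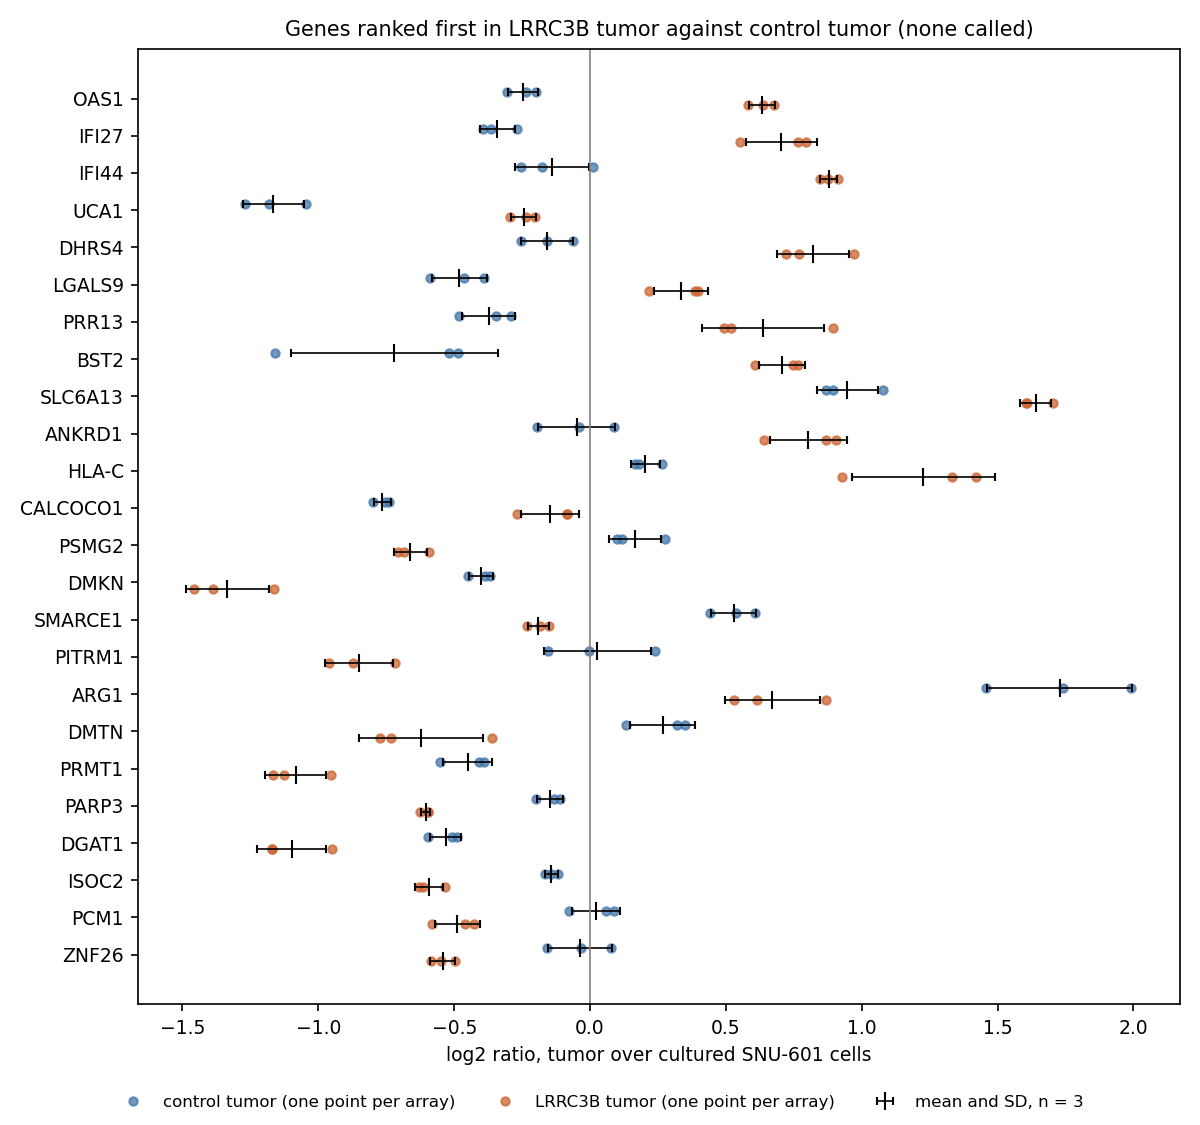
Log2 ratio of tumor over cultured SNU-601 cells (x axis) for the genes that ranked first in LRRC3B tumor against control tumor, one point per array, with the mean and SD of 3 arrays as a bar. The groups do not overlap for any gene drawn, as that was a condition for drawing it, and OAS1 lies at -0.25 in control tumors and 0.63 in LRRC3B tumors on average, though no gene passed the adjusted threshold.

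As a group, interferon response genes rose in LRRC3B tumors. The median difference over 23 measured members was 0.54, 21 members lay above 0, and camera gave an adjusted p of 8.35e-15, but adjusted p = 0.374 with an estimated correlation. Over all features 0 members were called, and 14 were adjusted over the list alone, including OAS1, IFI27, IFI44 and BST2. The mean over the list was -0.06 ± 0.04 (SD, n = 3) in control tumors and 0.52 ± 0.21 in LRRC3B tumors, where LRRC3B tumor 2 was lowest at 0.28. MHC class I and antigen processing genes also rose, with a median of 0.41 over 14 members, 13 of them above 0, an adjusted p of 9.60e-12, and adjusted p = 0.335 with an estimated correlation. Members called were 0 over all features and 9 adjusted over the list alone. HLA-C differed by 1.02 ± 0.14 and TAP1, which carries peptides into the endoplasmic reticulum, by 0.88 ± 0.13. The list means were 0.17 ± 0.02 in control tumors and 0.65 ± 0.10 in LRRC3B tumors. The exact two-sided permutation p of the list mean was 0.1, the smallest that 3 against 3 arrays allow, for interferon response, MHC class I, mitosis and the unfolded protein response. It was also 0.1 for 4 lists that camera did not call, namely endothelium, DNA replication, gastric and intestinal differentiation and immediate early genes, so it does not set the called lists apart. It was 0.2 for ribosomal proteins and for glycolysis, whose list means overlapped between the groups. By fry, which tests for a move one way, interferon response (adjusted p 0.0470), MHC class I (0.0331) and the unfolded protein response (0.0470) passed, and mitosis (0.282), ribosomal proteins (0.425) and glycolysis (0.440) did not.

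The unfolded protein response list rose slightly, with a median of 0.13 over 20 members and an adjusted p of 0.0383 by camera. Its adjusted p = 0.374 with an estimated correlation, and the call was lost without LRRC3B tumor 1, control tumor 1 or control tumor 2, with adjusted p of 0.0604, 0.0538 and 0.0736, and with arrays scaled (0.0649) or quantile-normalized (0.0628). Members called were 0 over all features and 0 adjusted over the list alone, and EDEM1 differed by 0.67 ± 0.15. Camera placed mitosis genes lower than other genes, without a move passing fry, with a median of -0.10 over 32 members (adjusted p 3.00e-04, and adjusted p = 0.534 with an estimated correlation). Members called were 0 over all features and 1 adjusted over the list alone, namely NDC80, a kinetochore protein, at -0.53 ± 0.10. It did the same for ribosomal protein genes, with a median of -0.14 over 63 members (adjusted p 1.00e-08, and adjusted p = 0.580 with an estimated correlation). Members called were 0 by either adjustment, and RPL17 differed by -0.43 ± 0.08. The ribosomal median was -0.08 without control tumor 2. It did so too for glycolysis genes, with a median of -0.08 over 15 members (adjusted p 0.0407, and adjusted p = 0.580 with an estimated correlation), with 0 members called by either adjustment and LDHA at -0.29 ± 0.12. That call was lost without LRRC3B tumor 2, control tumor 1 or control tumor 3, with adjusted p of 0.287, 0.0913 and 0.0718, and with cameraPR (0.0740). The glycolysis median ran from -0.15 without LRRC3B tumor 3 to -0.03 without LRRC3B tumor 2.

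The other 20 lists were not called, with adjusted p from 0.0525 to 0.984. Markers of other cell types were among them: the median difference was -0.01 for 15 myeloid genes, -0.04 for 7 lymphocyte genes, -0.11 for 24 fibroblast and matrix genes and -0.25 for 5 endothelial genes. MHC class II had a median of 0.06 over 11 members, and of them CD74 was called adjusted over the list alone, as was 1 immediate early gene. The class II median was 0.25 with a call without control tumor 2 (adjusted p 0.0283), but -0.04 without control tumor 3 and -0.04 without LRRC3B tumor 1. Several of the lists without a call gained one under other settings. Fibroblast and matrix was called lower with scaled arrays (median -0.28, adjusted p 6.64e-04), with quantile normalization (0.00445), without control tumor 2 (0.00245) and without LRRC3B tumor 1 (0.00989), while its median was -0.02 without LRRC3B tumor 3. Endothelium was called lower with quantile normalization (0.0436), the replicate block (0.0119) and without LRRC3B tumor 1 (0.0263) or 3 (0.0361), while its median was -0.06 without LRRC3B tumor 2. Hypoxia, cholesterol synthesis, DNA replication and immediate early genes each gained a call under at least 1 setting, with the smallest adjusted p at 0.00195, 6.16e-04, 0.0221 and 0.0154, so the absence of a call is not firm for these lists. The other lists without a call, with their medians, were immediate early genes (0.13), inflammatory cytokines (0.06), apoptosis regulators (0.05), complement (0.01), gastric and intestinal differentiation (0.00), TGF-beta and epithelial-mesenchymal transition (-0.02), Wnt targets (-0.02), oxidative phosphorylation (-0.02), cholesterol synthesis (-0.05), proteases (-0.05), DNA replication (-0.10) and hypoxia (-0.11). The TGF-beta list's mean was 0.01, opposite in sign to its median. For cell cycle inhibitors and p53 targets (0.03), heat shock (0.02) and epithelial junctions (0.03) the median lay above 0 while camera's direction was down, and the means were 0.00, -0.00 and 0.03. None of the 6 calls held with an estimated correlation. In simulations in which members of a list shared noise between arrays at a correlation of 0.3, the preset correlation called 7.45 of 25 unchanged lists on average, and the estimated correlation called 0. The interferon list, whose estimated correlation was 0.298, was called without any shift in 55% of those simulations with the preset correlation. With a shift of 0.5 the estimated correlation called it in only 5%, so in these simulations neither setting of camera settled the question. These simulations gave all genes 1 common spread, the root of the mean variance over features, and all lists the same correlation. The real lists' estimates ran from -0.05 for Wnt targets to 0.52 for MHC class II, so the rates need not hold for them. Fry called 0 unchanged lists and called the interferon list in 0% of those 20 simulations without a shift and in 5% with it, and it passed on the real list at 0.0470. Rates from 20 simulations are rough, so they do not show how much weight that pass carries.

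**Figure D2:**
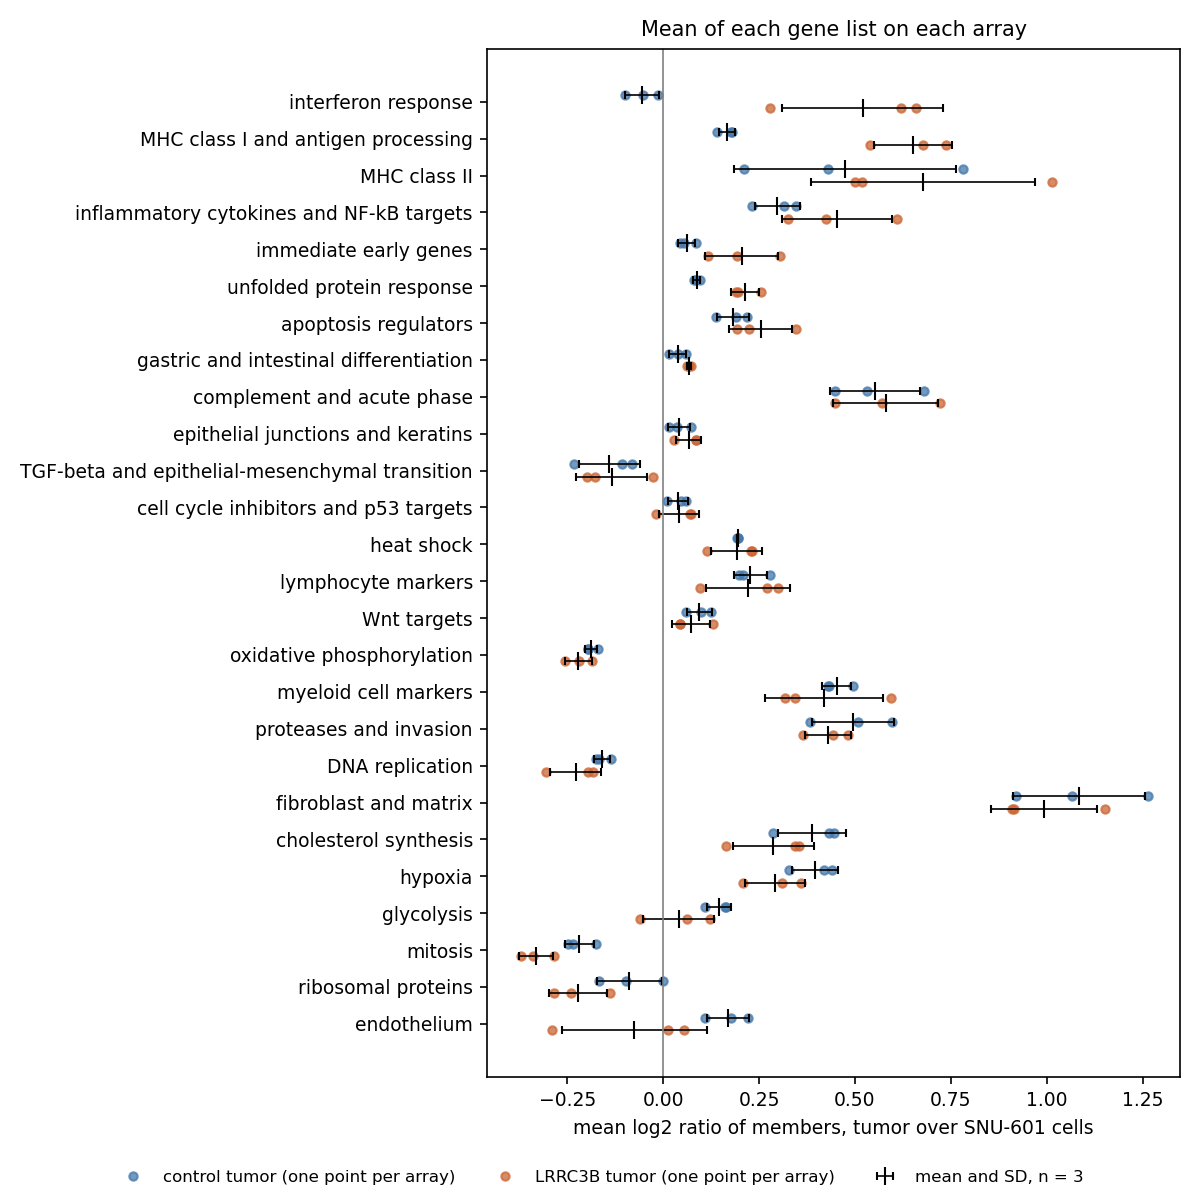
Mean log2 ratio over the members of each gene list (x axis) on each array, one point per array, with the mean and SD of 3 arrays as a bar, lists ordered by LRRC3B tumor minus control tumor. Interferon response lies at -0.06 in control tumors and 0.52 in LRRC3B tumors, while myeloid markers lie at 0.45 and 0.42.

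The second comparison set the tumors of both groups against the cultured cells. The tumors grew from SNU-601 given an empty vector or LRRC3B, while the labels name no vector for the reference cells. A difference made by the vector or by making the stable lines cannot be told from growth in the mouse. The collagen genes COL1A2, at 4.12 ± 0.12 (log2, SE, 6 arrays), and COL3A1, at 3.85 ± 0.46, led the genes that were higher in tumors. They were followed by HLA-DRB5, a class II antigen-presenting molecule (3.44 ± 0.27), SPP1, which encodes osteopontin (3.26 ± 0.16), SERPINF1 (2.96 ± 0.13), COL1A1 (2.88 ± 0.08), C1QB, a complement subunit made by macrophages (2.63 ± 0.16), HLA-DRB3 (2.57 ± 0.28), S100A9 (2.47 ± 0.20), FN1, which encodes fibronectin (2.36 ± 0.18), the complement inhibitor SERPING1 (2.29 ± 0.12) and MYH14 (2.28 ± 0.23). The genes lowest in tumors were the phospholipase PLA2G2A (-2.10 ± 0.14), E2F6 (-2.10 ± 0.06), CCK (-1.89 ± 0.06), ALDH3A1 (-1.88 ± 0.06), the transcription inhibitors ID3 (-1.79 ± 0.06) and ID2 (-1.66 ± 0.08), HPN (-1.62 ± 0.11), the ferritin light chain FTL (-1.51 ± 0.04), SLC13A1 (-1.48 ± 0.12), PSG5 (-1.34 ± 0.21), PSCA (-1.32 ± 0.11) and IFI30 (-1.26 ± 0.06).

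Limma called 5292 of 14297 features with Benjamini-Hochberg adjustment, 2778 higher and 2514 lower in tumors, of which 186 and 38 differed at least 2-fold. Of the 8798 genes tested 1817 were higher and 1663 lower, the share against which the counts of list members below are to be read. Without control tumor 1 the count was 3446. COL3A1 was 1.11 on control tumor 3 and 3.83 to 4.99 on the other arrays. Several values are means over probes that disagreed, with probes of FN1 from 0.36 to 4.22, of ALDH3A1 from -3.04 to 0.36 and of COL1A1 from 1.53 to 4.23. The same holds for SPP1 (2.53 to 4.75), C3 (0.11 to 2.54), FCGR3A (-0.10 to 1.39), IGHM (0.08 to 3.01), CXCL1 (0.04 to 1.56), VIM (-0.18 to 2.08), ID1 (-1.94 to 0.14), GDF15 (-1.55 to 0.02), CDH17 (-1.04 to 0.10) and CD44 (-0.19 to 1.10), and by the median adjusted p of their single probes CD74, C3, FCGR3A and MCAM lost the call. Human probes can also bind RNA of the mouse host, so a higher value does not tell tumor cells from host cells, and neither a dye effect nor the spread of the reference RNA was measured.

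**Figure D3:**
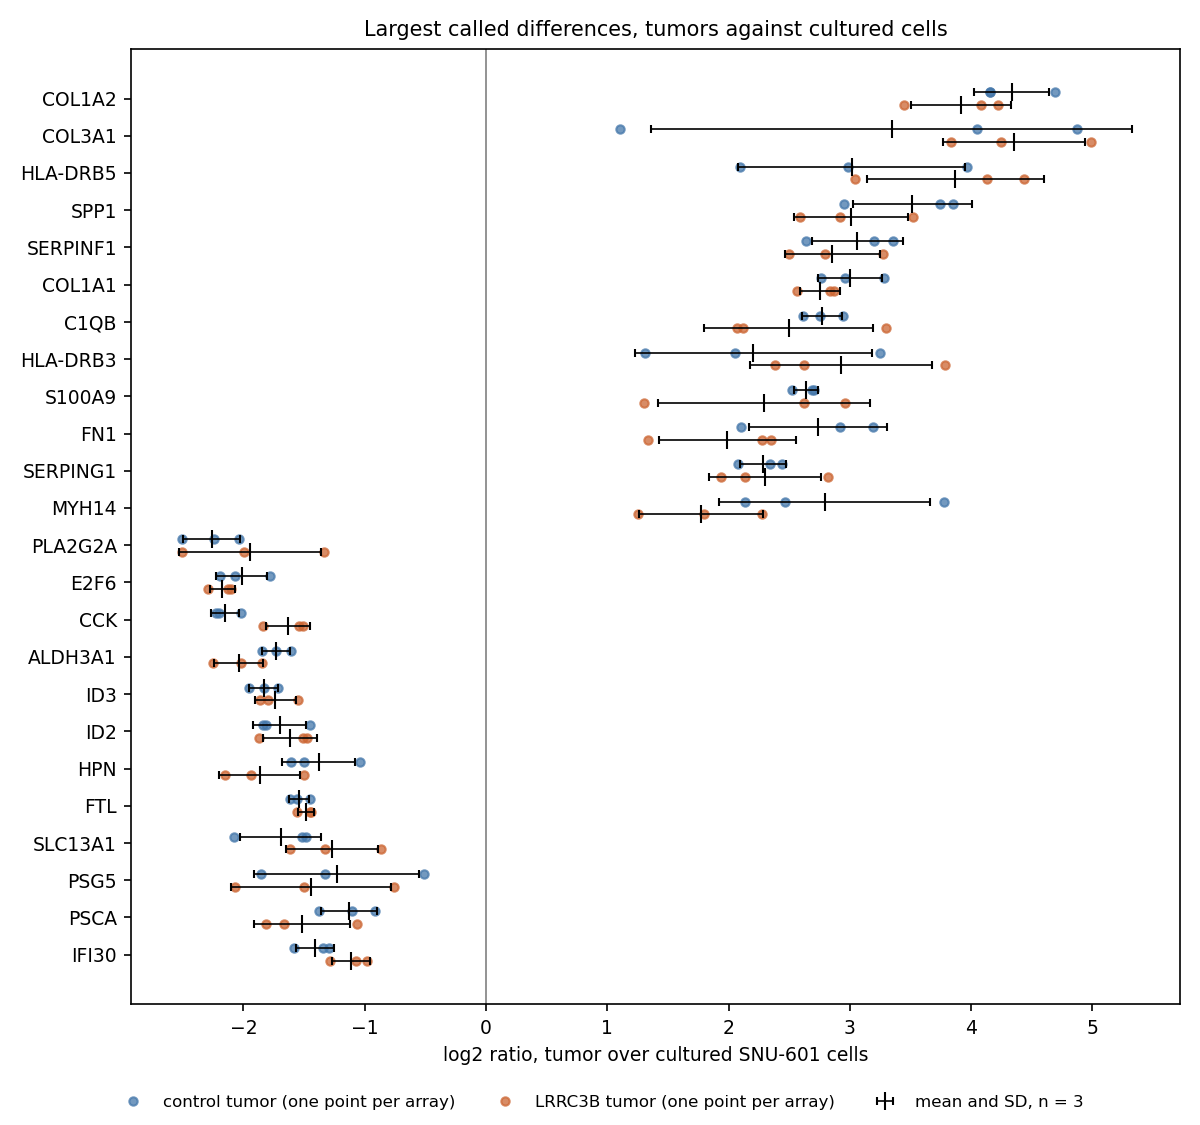
Log2 ratio of tumor over cultured SNU-601 cells (x axis) for the 12 genes with the largest and the 12 with the smallest mean ratio among those called, one point per array, with the mean and SD of 3 arrays as a bar. COL1A2 lies above 3 on every array, and COL3A1 is lowest on control tumor 3 at 1.11.

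Fibroblast and matrix genes rose in tumors: 17 of 24 measured members were higher and 0 lower, or 18 and 1 adjusted over the list alone. Beside the collagens, TAGLN, a smooth muscle protein, differed by 1.35 ± 0.08 and MMP2 by 0.83 ± 0.05. The list's median was 0.56, with an adjusted p of 7.89e-08 by camera and adjusted p = 0.242 with an estimated correlation. Complement and acute phase genes rose, with 8 of 15 members higher and 0 lower by either adjustment (adjusted p 0.00196, and adjusted p = 0.242 with an estimated correlation), among them CFB (1.69 ± 0.08), SERPING1, C1R (1.25 ± 0.08) and C3 (0.95 ± 0.07). Inflammatory cytokine and NF-kB target genes rose, with 10 of 18 higher and 0 lower by either adjustment, including NFKB1 (0.70 ± 0.05), the chemokines CXCL1 (0.75 ± 0.07) and CCL20 (1.00 ± 0.13), and IL1B (1.36 ± 0.18). That list's adjusted p was 0.00196, and adjusted p = 0.242 with an estimated correlation. Genes of the proteases and invasion list, which also holds genes other than proteases, rose, with 8 of 18 higher and 1 lower by either adjustment. CTSL (1.24 ± 0.06), the osteopontin gene SPP1 and the matrix metalloproteinase MMP7 (2.27 ± 0.14) led them. The list's adjusted p was 0.0145, was 0.0594 without control tumor 3, and adjusted p = 0.242 with an estimated correlation.

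Among antigen presentation genes, 11 of 14 MHC class I members were higher and 1 lower, or 11 and 2 adjusted over the list alone (median 0.38, adjusted p 1.85e-04, and adjusted p = 0.242 with an estimated correlation). PSMB10, an immunoproteasome subunit, differed by 0.92 ± 0.05, TAP1 by 1.08 ± 0.07, PSMB8 by 0.83 ± 0.07 and HLA-C by 0.71 ± 0.07. These values are means over both groups. The class I list mean was 0.17 in control tumors and 0.65 in LRRC3B tumors, so more of the rise comes from the LRRC3B tumors. Over both groups together interferon response genes rose, with 9 of 23 higher and 1 lower, or 11 and 1 adjusted over the list alone (adjusted p 0.00196, and adjusted p = 0.359 with an estimated correlation), led by GBP2 (1.17 ± 0.09), IFIT2 (0.58 ± 0.06), IRF7 (0.57 ± 0.06) and IFI44 (0.37 ± 0.05). The interferon list mean was -0.06 in control tumors, below 0 on each array, and 0.52 in LRRC3B tumors, so the list's rise comes from the LRRC3B tumors, although GBP2 was at 0.91 in control tumors. IFI44 was at -0.14 in control tumors and 0.88 in LRRC3B tumors. MHC class II as a list was not called (adjusted p 0.0655), although 5 of 11 members were higher and 2 lower, or 6 and 2 adjusted over the list alone. HLA-DPA1 (1.09 ± 0.11), CD74, the class II invariant chain (0.84 ± 0.09), HLA-DQB1 (1.46 ± 0.18) and HLA-DRA (1.25 ± 0.16) were among the 5. Each is a mean over probes that disagreed, from -0.37 to 2.56 for HLA-DPA1, -0.02 to 1.70 for CD74, -0.15 to 3.07 for HLA-DQB1 and 0.05 to 2.22 for HLA-DRA, which their SE does not include. Apoptosis regulators rose, with 10 of 24 higher and 1 lower by either adjustment (adjusted p 0.0236, and adjusted p = 0.242 with an estimated correlation). Those that led were the pro-apoptotic DIABLO (1.17 ± 0.09), the death ligand TNFSF10 (1.04 ± 0.10), APAF1 (0.35 ± 0.05) and BAD (0.56 ± 0.09).

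Hypoxia genes rose in tumors, with 14 of 25 members higher and 3 lower by either adjustment (median 0.32, adjusted p 5.49e-04, and adjusted p = 0.242 with an estimated correlation). The prolyl hydroxylases P4HA2 (1.10 ± 0.06), P4HA1 (0.83 ± 0.06) and EGLN3 (1.17 ± 0.07) and the oxidase ERO1A (0.63 ± 0.05) led them. Cholesterol synthesis genes rose, with 13 of 15 higher and 0 lower by either adjustment (median 0.36, adjusted p 5.57e-05, and adjusted p = 0.242 with an estimated correlation), among them HMGCS1 (0.55 ± 0.05), DHCR7 (0.61 ± 0.06), EBP (0.41 ± 0.05) and FDPS (0.29 ± 0.04). Mitosis genes fell, with 22 of 32 lower and 0 higher, or 23 and 0 adjusted over the list alone (median -0.27, adjusted p 2.58e-07, and adjusted p = 0.242 with an estimated correlation). STMN1 (-0.82 ± 0.07), the cyclin CCNA2 (-0.47 ± 0.04), CDC20 (-0.61 ± 0.06) and TTK (-0.47 ± 0.05) were examples. DNA replication genes fell, with 15 of 25 lower and 0 higher by either adjustment (adjusted p 5.49e-04, and adjusted p = 0.242 with an estimated correlation), including the DNA ligase LIG1 (-0.95 ± 0.06), POLD1 (-0.62 ± 0.07), MCM3 (-0.39 ± 0.06) and MCM7 (-0.39 ± 0.06).

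Oxidative phosphorylation genes fell, with 13 of 30 lower and 1 higher, or 16 and 1 adjusted over the list alone (adjusted p 5.57e-05, and adjusted p = 0.242 with an estimated correlation), led by COX6B1 (-0.64 ± 0.05), ATP5PF (-0.87 ± 0.07), UQCRH (-0.57 ± 0.05) and ATP5PO (-0.53 ± 0.04). Ribosomal protein genes fell, with 27 of 63 lower and 0 higher, or 28 and 1 adjusted over the list alone (adjusted p 1.44e-06, and adjusted p = 0.359 with an estimated correlation), led by RPS16 (-0.70 ± 0.06) and RPS18 (-0.53 ± 0.05). Ribosomal and HLA probes may bind paralogs. The 13 lists without a call had adjusted p from 0.0654 to 0.732. For several the absence of a call is not firm. MHC class II was called with cameraPR (0.0390), quantile normalization (0.0473), and without control tumor 3 (0.0334) or LRRC3B tumor 2 (0.0475). Myeloid markers were called with cameraPR (0.0385), scaled arrays (0.0471), quantile normalization (0.0473), the replicate block (0.0487) and without LRRC3B tumor 2 (0.0190). Heat shock was called with cameraPR (0.0367), the replicate block (0.0449), the median of a gene's probes (0.0178) and without LRRC3B tumor 3 (0.04998). The TGF-beta list was called with cameraPR (0.0384) and glycolysis without LRRC3B tumor 2 (0.0293). Fry, which does not compare a list with other genes, called all of the 13 but endothelium (0.214) and cell cycle inhibitors and p53 targets (0.770). Over all 8798 genes 1817 were higher and 1663 lower, so small counts of called members do not by themselves set a list apart. Of myeloid markers 4 of 15 were higher and 1 lower by either adjustment, with C1QB, S100A9, FCGR3A (0.65 ± 0.10) and CSF1R (0.38 ± 0.07) among the higher. Of lymphocyte markers LCK (0.79 ± 0.08) and IGHM (1.05 ± 0.12) were higher, of 7 measured, by either adjustment. Endothelial genes had 2 of 5 higher and 1 lower by either adjustment, namely MCAM (0.38 ± 0.07) and ENG (0.54 ± 0.11) against CLDN5 (-0.65 ± 0.11).

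Among the other lists without a call, glycolysis had 7 higher and 2 lower of 15 by either adjustment, with PGK1 at 0.52 ± 0.04 and LDHB at -0.54 ± 0.05. The unfolded protein response had 8 higher and 2 lower of 20 by either adjustment, led by DNAJB9 (1.01 ± 0.07). Heat shock had 6 higher and 3 lower of 18, or 8 and 3 adjusted over the list alone, led by DNAJB1 (0.77 ± 0.04). TGF-beta and epithelial-mesenchymal transition had 4 higher and 4 lower of 14 by either adjustment, with VIM, a mesenchymal filament protein, at 0.95 ± 0.05 and ID1 at -1.04 ± 0.05. Its median was 0.02 while its mean was -0.14 and camera's direction was down. Gastric and intestinal differentiation had 8 higher and 2 lower of 19 by either adjustment, with ANPEP at 0.65 ± 0.08 and CDH17 at -0.65 ± 0.07. Immediate early genes had 7 higher and 4 lower of 17, or 8 and 4 adjusted over the list alone, with JUN at 0.69 ± 0.06. Cell cycle inhibitors and p53 targets had 6 higher and 5 lower of 19, or 7 and 5 adjusted over the list alone, with GDF15 at -0.88 ± 0.05 and SESN1 at 0.79 ± 0.09. Epithelial junctions had 5 higher and 2 lower of 24, or 4 and 2 adjusted over the list alone, led by LAMB3 (0.96 ± 0.07), and Wnt targets had 3 higher and 0 lower of 12 by either adjustment, led by CD44 (0.42 ± 0.04). With 1817 of all 8798 genes higher and 1663 lower, such counts can arise in lists that do not stand out.

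Each tumor group was also set against the cells on its own. In control tumors limma called 2177 features, 1142 higher and 1035 lower, and in LRRC3B tumors 3870, 2157 higher and 1713 lower. COL1A2 was 4.33 ± 0.31 (SD, n = 3) in control tumors and 3.92 ± 0.41 in LRRC3B tumors, and SPP1 was 3.52 ± 0.49 and 3.01 ± 0.47. The control count was 485, 894 and 1287 without control tumor 1, 2 and 3, and the LRRC3B count was 1549 and 2359 without LRRC3B tumor 1 and 2. The gap narrowed to 2999 control against 3257 LRRC3B calls with scaled arrays. It was 2976 against 3387 with quantile normalization and 3754 against 3841 with array weights. The 2 counts do not show that the groups differ, since that difference was tested in the first comparison.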

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

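The tests of leukocytes, paralogs and spot position were chosen after the interferon result was seen; the counts over other splits of the arrays were planned before those splits were run. The bounds of these 3 tests first came from the spread between genes and were replaced by bounds from the spread between arrays after the first values were seen, which did not alter any verdict.

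The pattern weighed is the higher level of interferon response genes (adjusted p 8.35e-15) and MHC class I genes (9.60e-12) in LRRC3B tumors, picked out by camera's test of the difference between the groups, though neither held with an estimated correlation (adjusted p = 0.374 and adjusted p = 0.335). The prediction written for more leukocytes in those tumors was a rise of leukocyte markers by about as much. The 6 markers called higher in tumors than in cells had a median difference of -0.12. Its upper bound was 0.17, against 0.54 for the interferon list. The signal of these markers thus did not rise as much as the interferon list. Host leukocytes are mouse cells, however, and how fully human probes report them was not measured. The test therefore cannot decide on leukocytes, and a rise of them stays open. The 6 include FCGR3A and IGHM, whose probes disagreed. Signal shared between paralogs would leave genes without a near-identical relative at 0, and 15 such members had a median of 0.40 with a lower bound of 0.18. Spots whose numbers lay within 3 of the lists' probes had a median of -0.0105 against 0.53 for the probes. That argues against position on the array only if spot numbers follow the layout, which was not checked. An effect of LRRC3B, a difference between the injected cell lines that is unrelated to it, and interferon made by host cells stay open and were not tested, since the labels name 1 line per group.

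The 6 arrays form 10 splits into 3 and 3, too few for a share under 0.05. The interferon median of 0.54 was matched by 1 split, the real one, and the highest other was 0.35. For lists called, 2 splits reached the real value of 6, and the highest other gave 7. For features at an unadjusted p under 0.05, 2 splits reached 1443, and the highest other gave 1579 with control tumor 2, LRRC3B tumor 1 and LRRC3B tumor 2 set against the rest. For features past the adjusted threshold, all 10 splits reached the real count of 0, and the highest other was 0, which a real count of 0 fixes in advance. At an adjusted p under 0.10 the real split gave 9 features and each of the 9 others gave 0, a count for which no prediction had been written.

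Camera's test of the difference between the groups also picked out ribosomal proteins (adjusted p 1.00e-08), mitosis (3.00e-04), the unfolded protein response (0.0383) and glycolysis (0.0407), none of which held with an estimated correlation either. For 14 named genes every control array lay on one side of 0 and every LRRC3B array on the other, although limma's test of the difference did not pass. The naming rule took genes by small p, and those ranked first also by groups that did not overlap, so it favours such a separation. The share of all features that separate in this way was not counted. LRRC3B minus control was 0.88 for OAS1, 1.05 for IFI27, 0.98 for DHRS4, 0.81 for LGALS9, 1.01 for PRR13, 1.43 for BST2, 0.31 for BAK1, -0.83 for PSMG2, -0.72 for SMARCE1, -0.89 for DMTN, -0.18 for DUT, -0.34 for ATP5F1A, -0.43 for RPL17 and -0.37 for DNAJA1.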

How the results depend on the processing

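Counts are of features called. For LRRC3B against control tumors (0 in the design as fixed) 1 was called with only complete features, 1 with arrays scaled, 2 by single probes, 1 with robust eBayes, 13 with array weights, 9 at an adjusted p under 0.10, and 0 to 6 with an array left out. At an unadjusted p under 0.05 single probes gave 2354 and leaving out arrays 896 to 1707. For tumors against cells single probes gave 8997 (4596 higher, 4401 lower), the 2-fold limit 224 (186 and 38), and leaving out arrays 3446 to 4745 (1876 to 2508 higher, 1570 to 2237 lower). For control tumors against cells single probes gave 3873 (2082 and 1791), array weights 3754 (1902 and 1852), the 2-fold limit 196 (158 and 38), an adjusted p under 0.10 gave 1556 lower, and leaving out arrays 485 to 2237 (285 to 1167 higher, 200 to 1070 lower). For LRRC3B tumors against cells single probes gave 6798 (3571 and 3227), the 2-fold limit 272 (219 and 53), and leaving out arrays 1549 to 3694 (921 to 2086 higher, 628 to 1608 lower). Lists called fell from 6 to 0 with an estimated correlation and to 3 with fry in the first comparison, and from 13 to 0 and up to 24 in the second, and leaving out arrays gave 4 to 9 and 13 to 16. The single-probe counts rest on more features tested and those without an array on fewer arrays; for the others the cause was not tested. Whether replicate numbers pair the arrays is not settled. Deviations from the group mean correlated at 0.0128, 0.151 and 0.234 between groups for the same number, and at -0.198 to 0.0116 for different numbers. By these deviations 6 of 6 arrays correlated best with their own number in the other group. For number 1 the margin was slight, at 0.0128 against 0.0116 and 0.00829. The 6 are also not independent, since deviations within a group cancel and each correlation counts for an array of either group. A pairing by number stays open. With the replicate block 0, 5709, 2521 and 4320 features and 9 and 15 lists were called, and 2066 features at an unadjusted p under 0.05. Of named genes, 12 gene and setting pairs gained a call and 1156 did not alter in the first comparison, and 10 lost one and 1846 did not in the second, with 0 reversed. The alternatives for LRRC3B itself were not run, as no probe carried its name. The median of a gene's probes, chosen after seeing the data, gave 0 and 5155 calls. Signal over background was not analysed here, so what dim spots limit is unknown.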

Other observations

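The lists too small to test held genes that were higher in tumors than in cells. All 3 measured metallothioneins, which bind metal ions, were called higher by limma: MT1E by 1.45, MT1X by 0.81 and MT2A by 0.93. Haemoglobin beta, HBB, was higher by 1.46, while HBG1 was at -0.06. Myoglobin, MB, was higher by 0.33, and the adipocyte gene FABP4 was at -0.10.

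MHC class II and immunoglobulin probes varied between arrays of 1 group. A probe of HLA-DQB1 was 3.98 on control tumor 2 against 2.03 and 1.82 on control tumors 1 and 3, and 4.44 on LRRC3B tumor 1 against 3.33 and 2.80 on LRRC3B tumors 2 and 3. One of the 9 probes of IGHM was 3.49 on control tumor 2 against 2.26 and 1.74. A probe of CD74 was 0.48 to 1.64 in control tumors and 2.09 to 2.80 in LRRC3B tumors, while another CD74 probe was -0.23 to -0.10 and -0.16 to 0.53.

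The test of neighbouring spots was chosen after the disagreeing probes were seen. In 37 genes, 53 probes lay over 2 log2 units above the gene's lowest probe, such as probes of HADHB at 3.86 against -0.11, of SLC35F6 at 3.99 against -0.33 and of NFKBIZ at 3.76 against -0.17. Carry-over from a neighbouring spot could give this, but only 10 of the 53 had a directly neighbouring spot within 1 log2 unit or higher. Some of the 10 were not high themselves, such as probes of ID1 at 0.14 and 0.13 against -1.94. For those a neighbour without a high signal was enough to be counted. The exact 95% upper bound was 32.0%, which takes the probes as independent although some genes gave several. Neighbours were taken by spot number, and whether these numbers follow the layout was not checked. A clone with another identity than its annotation, or transcripts that only some probes cover, stay open and were not tested.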
